A study of Mus musculus with 111 samples.

How the data were processed

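Gene expression was measured by RNA sequencing in bone marrow-derived macrophages of 10-week-old female mice of 28 strains. Per the labels' protocols, marrow was grown for 7 days in medium with 20% L929-conditioned supernatant and frozen, and thawed cells were plated overnight in that medium before treatment. RNA was selected by its poly-A tail and sequenced on an Illumina HiSeq 2000 with 4 libraries per lane; which libraries shared a lane is not given. One sentence of the extraction protocol speaks of retinas, which no other label mentions. Treatment, time and strain came from the sample titles and tags. In 1 sample of the IFN/TNF group the title gives strain Bxa26 and the strain tag Bxa25; the title was followed, and the library was left out as an alternative.

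The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to each library's fragments) for 25791 genes in 111 columns. Reads were aligned to the mm9 mouse genome with TopHat2 2.0.4 and quantified with Cufflinks 2.0.0, per the submitters' processing notes. The columns were matched to samples by their headers, and all 111 were used. Every IFN/TNF column was identical to the CpG column of its strain in all 25791 genes (28 pairs), so 83 distinct libraries in 3 groups were analysed, each pair once under the name stimulated. The fit had been planned for 111 libraries in 4 groups; the comparison of IFN/TNF with CpG was not possible, and which stimulus the values belong to is not known. FPKM columns summed to 367244 to 710897 in the non-stimulated, 491198 to 659217 in the infected and 383703 to 589849 in the stimulated libraries. In 73 genes with a median of at least 10 FPKM in a group, 290 single values of that group stood at exactly 0. Such a value can be a failed estimate of the quantification program, so these values were also taken as missing, as an alternative. A gene listed at 0 in most libraries of a group has a median of 0 there, and was neither counted nor taken as missing. Fth1 and Rn18s in the stimulated libraries are examples, and they stayed in the fits.

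FPKM carry no counts. The depth of 80 of the 83 libraries was estimated from the 2275 genes of low level with a single transcript over 800 bases in the GENCODE transcripts supplied, as the number of fragments at which 1 fragment on such a gene gives the most common value, and it is approximate. Non-stimulated libraries above 30000000 fragments (5) were set apart from the 23 others, a split by depth chosen after the data were seen. Transcript lengths were those of the longest GENCODE transcript of each symbol, which 84.2% of tested genes had. Coordinates are those of the deposited table on mm9; its starts count from 0, as 6545 of 20000 gene spans equalled in length the span in the RefSeq table supplied under that reading and 132 under the other, and were written here counting from 1.

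All tests used R 4.3.3 with limma 3.58.1, and the other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Values were transformed to log2(FPKM + 1), a scale that understates the differences of genes at low levels. Genes with at least 1 FPKM in at least 27 libraries (11395) were tested. Treatments were compared in 1 limma fit with a mean per treatment, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. In the comparisons of treatments and of the parents, a gene was called at an adjusted p under 0.05 with a log2 difference of at least 1 in either direction. The strain effect was the limma F-test of the 27 strain terms beside treatment, called on adjusted p alone, and B6 against AJ was a contrast of that fit. BxA and AxB strains (13 each) were compared on 1 value per strain, the mean over treatments, and on each strain's response for the test of cross by treatment; both were called on adjusted p alone. The replicates are strains, with 1 library per strain and treatment, so p-values measure only the spread between these samples. The contrast of infected with stimulated libraries was added after the data were seen and forms a family of its own.

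For the pairing check, each library's deviation from its treatment mean was correlated, over 500 genes with the largest strain effect in the other treatments, with the libraries of its own and of every other strain. In the 77 libraries of recombinant inbred strains the correlation with the own strain was 0.46 to 0.89, with a median of 0.8, and it was the highest for 76 of them. Strain thus pairs the libraries; the fits above leave this block out, and a fit with it was run as an alternative.

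Before the data were examined, 36 gene lists, the rule for named genes, the tests and the first set of alternatives were fixed. The 30 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 60 tests of the 2 treatment comparisons, and again with an estimated correlation and with fry. The list of mitochondrially encoded genes had no member in the table. Marker lists of 8 other cell types were compared by the mean log2(FPKM + 1) of their members with a 2-sided permutation test (100000 permutations, 16 tests). Named genes were the 10 largest rises and falls per treatment comparison (8 in the direct one) among called genes with a mean of at least 10 FPKM that moved the same way in at least 95% of strains, up to 4 members of each list, and 8 genes fixed by name (Apobec1, Apobec3, Adar, Rbm47, A1cf, Nos2, Arg1 and Tlr9). They also included the 12 genes with the largest strain effect, 8 in each direction between the parents and 5 between the crosses. Few other genes (Y-linked genes, Xist and single genes of the closing part) were chosen after their values were seen. Levels of 4 lists were correlated between treatments over the recombinant inbred strains (12 relations, Pearson and Spearman, 2-sided permutation p). Variance shares are sums of squares of treatment, strain and residual, with a standard error over strains.

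The methods were first tested on simulated data with the means and spread of the real libraries and 200 changed genes of 11395. Of 100 genes changed by 1.5 log2, 100 were recovered for stimulated, 99 for infected and 90 for B6 against AJ, with 0, 1 and 2 false calls. Of 100 genes with a strain SD of 0.5, 93 were recovered (9 false calls). Of 100 genes changed by 1 log2, 98 were recovered between the crosses (11 false calls) and 91 in cross by treatment (3 false calls). A raised list was called and 0 of the other lists were.

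Alternatives fixed in advance were strain as a block, a pseudocount of 0.1, no filter, a minimum of 5 FPKM, scaling to the same median, quantile normalization, recombinant inbred strains alone, fits of 2 groups, a trended and robust variance, no minimum difference, leaving out each treatment and leaving out the library with conflicting labels. Alternatives chosen after seeing the data were the deep or the other controls alone, the missing values at 0, and leaving out the stimulated libraries labelled AJ and B6 or the infected libraries of Bxa2 and Bxa11. Splicing and RNA editing need reads and were not analysed here.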

Results

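Messenger RNA was sequenced from bone marrow-derived macrophages of 26 recombinant inbred mouse strains, 13 AxB and 13 BxA, and of their parents AJ and B6. Each recombinant inbred strain carries a fixed mosaic of the 2 parental genomes, and there was 1 library per strain and treatment. From its title, the series asks how genetic background shapes splicing and the activity of APOBEC1, the cytidine deaminase that edits mRNA. The labels list 28 non-stimulated libraries, 28 stimulated with IFN/TNF for 18 h, 28 stimulated with CpG for 18 h and 27 infected libraries at 8 h, from which strain Axb8 is absent. The infecting agent is given as type II, Pru A7; Pru is a type II strain of the parasite Toxoplasma gondii. The IFN/TNF and the CpG values of every strain were identical in all 25791 genes, so that 83 distinct libraries remained. Those 28 libraries are called the stimulated libraries here, their stimulus is left open, and the 2 stimuli could not be compared.

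The deposited values were FPKM, and the depth was estimated from the step that 1 fragment makes in them. The infected libraries held about 6500000 to 18900000 fragments and the stimulated libraries about 36250000 to 68590000. The non-stimulated libraries fell into 5 deep libraries of 36250000 to 65800000 fragments (Axb13, Axb15, Bxa16, Bxa25 and Bxa26) and 23 others, 20 of which had an estimate, of 11790000 to 24930000 fragments. The 5 deep libraries differed from the 23 others at 716 of the 11395 genes tested, and the difference rose with transcript length across genes (rho = 0.53), where genes are not independent replicates. Values against either set of controls are therefore given beside genes named as changed where they ended the call. Lists were tested again with the 23 other controls only, and against the 5 deep ones only their medians were taken.

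The stimulated and non-stimulated libraries were compared to find which macrophage genes responded to 18 h of stimulation in a panel of genetic backgrounds. Il1b, which encodes the inflammatory cytokine interleukin-1 beta, stood at 0.885 ± 2.65 FPKM (SD, n = 28) without stimulation and at 734 ± 390 FPKM (n = 28) with it, a rise of 8.74 ± 0.20 (SE) on the log2(FPKM + 1) scale with an adjusted p of 6.94e-57. The control mean of Il1b was raised by 1 library, Bxa26, at 14.2 FPKM, and the control median was 0.319 FPKM. Lcn2, an antimicrobial protein that binds bacterial iron carriers, rose by 8.04 ± 0.15 to 368 ± 270 FPKM (adjusted p = 1.03e-63). Birc5, which encodes the mitotic protein survivin, fell by 3.63 ± 0.15 from 53 ± 20.6 to 3.38 ± 1.83 FPKM (adjusted p = 7.14e-37). Each of these 3 genes moved in the same direction in 28 of 28 strains.

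In all, 702 genes rose and 1037 fell of 11395 tested. Both stimulated and control libraries were scaled only by their FPKM, and the median gene lay at -0.16 log2 (-0.06 with each library set to the same median and -0.04 with quantile normalization). With each library set to the same median, 821 rose and 822 fell, and with quantile normalization 834 rose and 742 fell. The balance of rises and falls therefore depended on the scaling, while the genes named as rising or falling kept their call under both scalings unless stated. The other rises among the 10 largest, each as a log2 difference ± SE, were Cxcl3 (7.96 ± 0.22), a neutrophil-attracting chemokine, U90926 (7.65 ± 0.15), Marco (7.17 ± 0.17), a scavenger receptor, Mmp14 (7.14 ± 0.13), a membrane-bound protease, Serpinb2 (6.82 ± 0.14), Il1a (6.80 ± 0.23), Socs3 (6.64 ± 0.08), a feedback inhibitor of cytokine receptors, and Irg1 (6.50 ± 0.22), the enzyme that makes itaconate. Saa3, an acute-phase protein, reached a median of 15299.2 FPKM in the stimulated libraries against 5.58 FPKM in the controls, but was listed at 0 in 3 stimulated libraries. The largest falls included Stmn1 (-4.02 ± 0.16), a microtubule regulator, Pcp4l1 (-3.71 ± 0.18), Ccna2 (-3.50 ± 0.15) and Ccnb2 (-3.46 ± 0.14), 2 cyclins of cell division, Rasgrp3 (-3.48 ± 0.13), Rgs2 (-3.35 ± 0.13) and Fam64a (-3.31 ± 0.14). The histone gene Hist1h2ao fell by 4.18 ± 0.28 in 27 of 28 strains, and by 1.57 against the 5 deep controls alone. Fth1, the ferritin heavy chain, had a median of 11883.3 FPKM without stimulation and was listed at 0 in all 28 stimulated libraries. No fold is given for it, although it stayed in the fit.

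Inflammatory gene groups rose together in the stimulated libraries. Of 16 inflammatory cytokine genes tested, 12 rose and 0 fell (median 2.25, camera adjusted p = 7.29e-10), among them Csf3 (4.94 ± 0.13), the granulocyte colony-stimulating factor, and Il1rn (3.57 ± 0.17), the interleukin-1 receptor antagonist. Of 20 chemokines, 16 rose and 1 fell (median 2.02, adjusted p = 1.17e-08), with Cxcl2 at 6.32 ± 0.14, Cxcl1 at 5.85 ± 0.24 and Ccl5 at 3.86 ± 0.30. Of 28 NF-kB target and feedback genes, 22 rose and 1 fell (median 1.77, adjusted p = 3.83e-20), including Ptgs2 (4.31 ± 0.21), the inducible cyclooxygenase, Nfkbiz (4.05 ± 0.13) and Ier3 (4.04 ± 0.09). Of 25 antimicrobial effectors, 16 rose and 1 fell (median 2.64, adjusted p = 2.33e-13), Lcn2, Marco and Irg1 among the rises. All 5 tested neutrophil markers rose (median 4.19, adjusted p = 3.53e-07), with S100a8 going from 6.09 ± 5.49 to 135 ± 145 FPKM, Mmp9 rising by 5.10 ± 0.20 and Mmp8 by 4.19 ± 0.11. The list has 16 markers, of which 6 had a median of at least 1 FPKM with stimulation and 2 without it. The 28 stimulated libraries alone could meet the filter, so a marker could be tested because it rose. Lcn2 stands on both of the last 2 lists, and Mmp9 on the osteoclast list too. These 5 lists kept their call with an estimated correlation between members (adjusted p of 0.013 for cytokines, chemokines and NF-kB genes and 0.0049 for antimicrobial effectors and neutrophil markers). For all 30 lists with at least 3 tested members, the counts adjusted over the list alone equalled those over all genes tested in the 3 treatment comparisons.

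Interferon-related and sensing lists moved by smaller medians. Of 18 GTPases inducible by interferon gamma, 7 rose and 0 fell (median 0.44, adjusted p = 6.91e-04; adjusted p = 0.666 with an estimated correlation), led by Gbp5 (2.60 ± 0.17) and Gbp6 (2.49 ± 0.14), which act against vacuolar pathogens. Of 30 type I interferon-stimulated genes, 4 rose and 0 fell (median 0.50, adjusted p = 9.52e-04; adjusted p = 0.734 with an estimated correlation), namely Mx1 (1.84 ± 0.19), Mx2 (1.57 ± 0.16), Oas2 (1.38 ± 0.12) and Zbp1 (1.29 ± 0.19). Oas2 differed by 0.66 against the 5 deep controls, short of the size required. Toll-like receptors and adaptors (3 of 21 rose; adjusted p = 0.00732, median 0.16, and -0.25 against the 5 deep controls, and adjusted p = 0.656 with an estimated correlation) included Tlr1 (2.65 ± 0.09) and Tlr2 (1.75 ± 0.13), sensors of bacterial lipoproteins. Inflammasome genes (4 of 19 rose; adjusted p = 0.0015, median 0.46, and 0.13 against the 5 deep controls, and adjusted p = 0.47 with an estimated correlation) included Mefv (2.44 ± 0.11), Nlrp3 (1.81 ± 0.11) and Nlrc4 (1.63 ± 0.14). Of 23 immediate early and MAPK feedback genes, 6 rose and 1 fell (adjusted p = 0.00415, median 0.41, and 0.03 against the 5 deep controls; adjusted p = 0.524 with an estimated correlation), with Phlda1 at 2.42 ± 0.12 and the falling Klf2 at -1.66 ± 0.14. Of 18 NRF2 targets, 4 rose and 0 fell (median 0.61, adjusted p = 0.00411; adjusted p = 0.632 with an estimated correlation), including Slc7a11 (3.24 ± 0.13), the cystine importer, and Hmox1 (2.12 ± 0.13), heme oxygenase.

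Proliferation genes fell together. All 30 cell cycle genes fell (median -2.30, adjusted p = 1.29e-13; adjusted p = 0.24 with an estimated correlation). Oxidative phosphorylation genes lay lower as a list (median -0.68, -0.41 against the 5 deep controls and -0.39 with quantile normalization; adjusted p = 6.98e-05; adjusted p = 0.666 with an estimated correlation), although only Cox4i1 of 29 fell past the size required (-1.01 ± 0.10; -0.25 against the 5 deep controls and -0.59 with quantile normalization, both short of it). Of 18 genes of the tricarboxylic acid cycle, Mdh1 (-1.16 ± 0.05) and Suclg2 (-1.02 ± 0.06) fell (adjusted p = 0.0275, median -0.31, and -0.11 with quantile normalization; adjusted p = 0.718 with an estimated correlation and 0.332 with quantile normalization). With quantile normalization Mdh1 and Suclg2 differed by -0.93 and -0.96, short of the size required, as did Suclg2 against the 23 other controls (-0.98).

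The remaining lists did not pass the test in the stimulated libraries. Of 25 macrophage identity genes, 6 rose and 5 fell (adjusted p = 0.379; the median was -0.26 while the test pointed upward), with Itgam (3.07 ± 0.14), the complement receptor subunit CD11b, and Emr1 (2.28 ± 0.10), which encodes the F4/80 antigen, rising and Cx3cr1 (-2.81 ± 0.22) falling. Of 18 alternative activation genes, 5 rose and 6 fell (adjusted p = 0.801; median -0.11 with an upward test), among them Il4ra (2.94 ± 0.12), Folr2 (-2.62 ± 0.17) and Trem2 (-2.58 ± 0.09). Arg1, arginase 1, rose by 2.48 ± 0.32 in 27 of 28 strains, but its difference of 1.32 against the 5 deep controls did not pass the test (adjusted p = 0.0656). Lysosomal genes went both ways (1 of 26 rose, 5 fell; adjusted p = 0.624), with the acid lipase Lipa at -2.21 ± 0.08. Against the 5 deep controls Itgam, Cx3cr1, Tlr2 and Pfkfb3 differed by 2.03, -4.63, 1.05 and 1.14. For MHC class II presentation 1 of 9 rose (H2-Ab1, 2.15 ± 0.20; adjusted p = 0.379), and for MHC class I and the immunoproteasome 1 of 16 rose (adjusted p = 0.596; median -0.05 with an upward test). For glycolysis 3 of 19 rose (adjusted p = 0.0912, and 0.00906 with quantile normalization), including Pfkfb3 (2.28 ± 0.14), and for cholesterol biosynthesis 1 of 22 fell (adjusted p = 0.363). LXR targets (2 of 15 rose; adjusted p = 0.423; median -0.11 and mean 0.13), integrated and ER stress genes (3 of 18 fell; adjusted p = 0.922; median -0.24 with an upward test), SR proteins (2 of 20 rose; adjusted p = 0.539) and hnRNPs with other splicing regulators (1 of 35 rose and 1 fell; adjusted p = 0.922) did not pass. Genes polymorphic between AJ and B6 (3 of 14 rose, 1 fell; adjusted p = 0.283), dendritic cell markers (2 of 5 rose; adjusted p = 0.143) and osteoclast markers (2 of 7 rose, 1 fell; adjusted p = 0.379; median -0.24 and mean 0.75) did not either.

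The calls came from limma with 1 mean per treatment over 83 libraries, an adjusted p under 0.05 and a log2 difference of at least 1. Against the 5 deep controls alone, 1095 of the 1739 genes kept their call and 36 had the opposite sign. The stimulated libraries were also the deepest, and their differences rose with transcript length across genes (rho = 0.34), so that depth and stimulation were confounded against the 23 other controls.

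**Figure D1:**
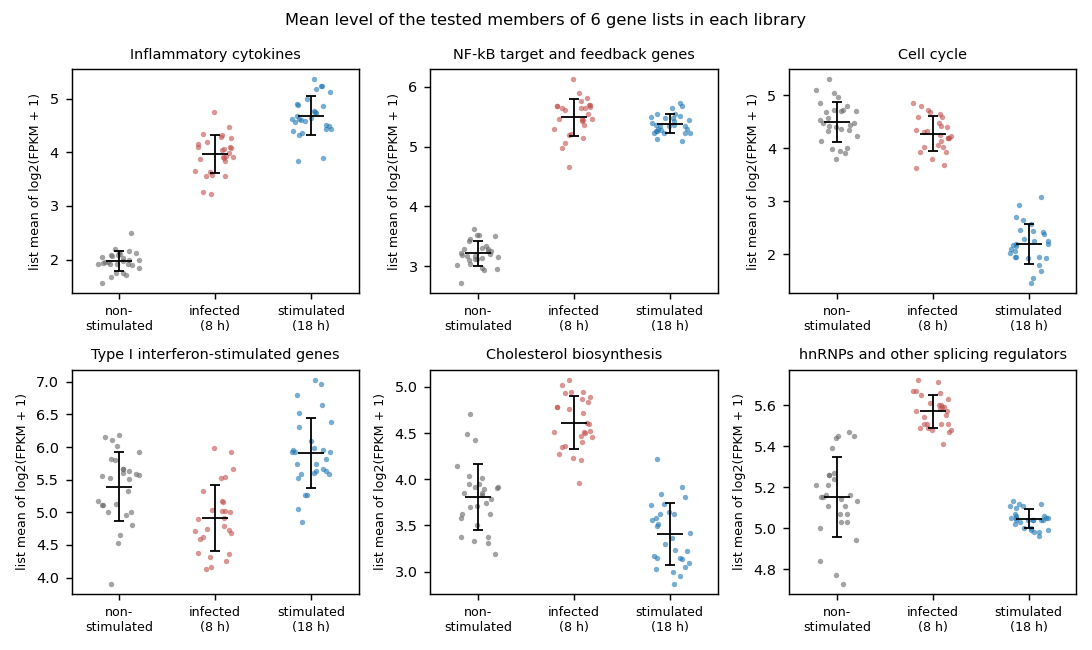
Mean log2(FPKM + 1) of 6 gene lists in each library (points) of the non-stimulated, infected and stimulated groups, with the group mean and SD (bar and whisker). The cell cycle list lay between 1.46 and 3.08 in the stimulated libraries, below all non-stimulated libraries (3.80 to 5.30).

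The infected and non-stimulated libraries were compared to find the response to 8 h of infection. Il1b rose by 6.51 ± 0.20 (SE), from 0.885 ± 2.65 FPKM (SD, n = 28; median 0.319, the mean being raised by Bxa26 at 14.2) to 145 ± 65.6 FPKM (n = 27), with an adjusted p of 4.28e-47. Slc16a1, which encodes the lactate transporter MCT1, rose by 3.01 ± 0.07 from 7.61 ± 1.49 to 68.2 ± 11.7 FPKM (adjusted p = 2.46e-57). Hnrnpf, an RNA-binding regulator of splicing, rose by 1.45 ± 0.04 from 159 ± 18.9 to 436 ± 44.4 FPKM (adjusted p = 2.12e-47). Rtp4, an interferon-stimulated gene, fell by 1.84 ± 0.09 from 102 ± 23.6 to 28 ± 7.49 FPKM (adjusted p = 9.10e-32), and Txnip, an inhibitor of thioredoxin and of glucose uptake, fell by 3.08 ± 0.16 from 84.3 ± 37.9 to 9.94 ± 6.31 FPKM (adjusted p = 1.98e-30).

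Infection raised 749 genes and lowered 472 of 11395 tested. The other rises among the 10 largest were Cxcl2 (5.76 ± 0.14), Ptgs2 (5.49 ± 0.21), Ccl24 (5.34 ± 0.11), an eosinophil-attracting chemokine, Gja1 (5.32 ± 0.15), a gap junction protein, Cxcl1 (4.98 ± 0.24), Clec7a (4.77 ± 0.17), the beta-glucan receptor Dectin-1, and Ier3 (4.73 ± 0.09). Adm (4.65 ± 0.12), the vasodilator peptide adrenomedullin, and Socs3 (4.57 ± 0.09) completed them. The other largest falls were Cx3cr1 (-2.67 ± 0.22; -4.48 against the 5 deep controls), the fractalkine receptor, Rasgrp3 (-2.56 ± 0.13), Arl11 (-2.52 ± 0.10), Pdgfb (-2.48 ± 0.16), Hmg1l1 (-2.42 ± 0.08), Cspg4 (-2.34 ± 0.16), Prc1 (-2.33 ± 0.13), Mocos (-2.26 ± 0.10) and Mical1 (-2.18 ± 0.08).

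Among the lists, 22 of 28 NF-kB target and feedback genes rose and 0 fell (median 2.14, adjusted p = 2.33e-18; adjusted p = 0.0138 with an estimated correlation), including Cd83 (4.29 ± 0.12), a marker of maturing antigen-presenting cells. Of 20 chemokines, 14 rose and 1 fell (median 2.66, adjusted p = 4.02e-08; adjusted p = 0.0138 with an estimated correlation), with Ccl17 at 4.56 ± 0.20. Of 16 inflammatory cytokines, 11 rose and 0 fell (median 1.51, adjusted p = 1.90e-05; adjusted p = 0.121 with an estimated correlation), among them Osm (3.58 ± 0.11), Il1a (3.57 ± 0.23) and Il1rn (3.49 ± 0.17). Of 23 immediate early and MAPK feedback genes, 13 rose and 2 fell (median 1.15, adjusted p = 2.63e-04; adjusted p = 0.33 with an estimated correlation), including the transcription factors Egr1 (4.35 ± 0.11), Egr3 (3.71 ± 0.10) and Egr2 (3.54 ± 0.13). The type I interferon-stimulated genes went the other way: 0 of 30 rose and 6 fell (adjusted p = 0.028, median -0.35, and -0.23 against the 5 deep controls; adjusted p = 0.877 with an estimated correlation and 0.0525 with quantile normalization), among them Oasl2 (-1.64 ± 0.12) and Irf9 (-1.43 ± 0.07), a subunit of the interferon-activated transcription complex.

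Metabolic and RNA-processing genes also moved. Of 22 cholesterol biosynthesis genes, 10 rose and 0 fell (median 0.94, adjusted p = 1.29e-04; adjusted p = 0.656 with an estimated correlation), with Cyp51 at 1.53 ± 0.13, Sc5d at 1.38 ± 0.09, Hsd17b7 at 1.32 ± 0.09 and Lss at 1.23 ± 0.10. Of 35 hnRNPs and other splicing regulators, 3 rose and 0 fell (adjusted p = 2.15e-05, median 0.40, and 0.09 against the 5 deep controls; adjusted p = 0.47 with an estimated correlation). They were Hnrpll (1.94 ± 0.05), Hnrnpf and Hnrnpa3 (1.04 ± 0.08), the last at 0.96 with quantile normalization and against the 23 other controls, short of the size required. The 20 SR proteins, which guide splice site choice, lay higher as a list with 0 members past the size required (adjusted p = 0.04, median 0.47, and 0.11 against the 5 deep controls; adjusted p = 0.666 with an estimated correlation and 0.0647 with quantile normalization). Of 18 NRF2 targets, 5 rose and 0 fell (median 0.60, adjusted p = 0.00519; adjusted p = 0.641 with an estimated correlation), including Slc7a11 (3.23 ± 0.13), Txnrd1 (1.72 ± 0.08) and Gclm (1.57 ± 0.13).

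The other lists did not pass the test in the infected libraries. Macrophage identity genes included 8 falls and 0 rises among 25 (median -0.33, adjusted p = 0.129), among them the complement genes C1qa (-1.44 ± 0.32) and C1qc (-1.19 ± 0.31); with strain as a block the list passed (adjusted p = 0.0494). Of 18 alternative activation genes 7 rose and 1 fell (adjusted p = 0.26), including the mannose receptor Mrc1 (3.11 ± 0.24) and Arg1 (2.62 ± 0.32; 1.46 against the 5 deep controls). Of 25 antimicrobial effectors 6 rose and 2 fell (adjusted p = 0.26), with Irg1 at 4.23 ± 0.23 and Slc7a2 at 3.82 ± 0.19, an arginine transporter. LXR targets went both ways (5 of 15 rose, 4 fell; adjusted p = 0.777); Abca1, the cholesterol exporter, rose by 1.58 ± 0.17 but lay at -0.07 against the 5 deep controls. Cell cycle genes (2 of 30 rose, 1 fell; adjusted p = 0.363) included the replication helicase subunit Mcm2 (1.23 ± 0.10) and the mitotic motor Kif11 (-1.13 ± 0.14). GTPases inducible by interferon gamma (3 of 18 rose; adjusted p = 0.685), inflammasome genes (3 of 19 rose, 2 fell; adjusted p = 0.695), Toll-like receptors and adaptors (2 of 21 rose, 1 fell; adjusted p = 0.896) and integrated and ER stress genes (3 of 18 rose; adjusted p = 0.423) contained Gbp5 (2.77 ± 0.17), Nlrp3 (2.20 ± 0.11), Tlr1 (2.15 ± 0.09) and Phgdh (2.38 ± 0.14), the first enzyme of serine synthesis. Of 26 lysosomal genes 3 fell (adjusted p = 0.0694), with Ctsh at -1.27 ± 0.18 (-1.94 against the 5 deep controls). The lysosomal list passed with strain as a block (adjusted p = 0.0494) and with abundant values at 0 replaced by the group mean (adjusted p = 0.0464). No member of MHC class II presentation (adjusted p = 0.762), oxidative phosphorylation (adjusted p = 0.0869), the tricarboxylic acid cycle (adjusted p = 0.922) or the neutrophil markers (adjusted p = 0.948; median 0.02 and mean -0.06) passed. The oxidative phosphorylation list passed, as lower, with quantile normalization (adjusted p = 0.00906) and against the 23 other controls (adjusted p = 0.0104; median -0.24), while its median was -0.17 in the main fit and 0.09 against the 5 deep controls. MHC class I (1 of 16 rose; adjusted p = 0.833), glycolysis (2 of 19 rose; adjusted p = 0.695; median -0.03 and mean 0.18), genes polymorphic between AJ and B6 (2 of 14 rose, 1 fell; adjusted p = 0.448), dendritic cell markers (3 of 5 rose; adjusted p = 0.0912) and osteoclast markers (1 of 7 rose; adjusted p = 0.717) did not pass either.

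Marker genes of other cell types also differed between the groups. The mean level of 15 fibroblast markers was 0.119 ± 0.119 (SD, n = 28) log2(FPKM + 1) in the non-stimulated and 0.518 ± 0.175 (n = 27) in the infected libraries, a difference of 0.40 (permutation test, 2-sided, adjusted p = 2.29e-05 over 16 tests of cell types; p = 1.00e-05, the smallest possible). In the stimulated libraries it was 0.245 ± 0.0557 (n = 28), a difference of 0.13 (adjusted p = 2.29e-05). Dcn, one of these markers, had a median of 3.42 FPKM there, 0.821 in the infected and 0.112 in the non-stimulated libraries. Medians of other fibroblast markers went both ways with stimulation. That of Lum was 0.24 FPKM against 0 without it, and that of Col1a2 was 0.0358 against 0.0793 FPKM. Ddx3y, a gene of the Y chromosome, had a median of 0.112 FPKM in the infected libraries, although the labels give female mice. Neutrophil markers had a mean of 0.386 ± 0.11 in the non-stimulated and 1.95 ± 0.226 in the stimulated libraries (difference 1.57, adjusted p = 2.29e-05) and differed by -0.03 in the infected ones (adjusted p = 0.271). Dendritic cell markers were higher by 0.23 with stimulation and 0.49 with infection, and osteoclast markers by 0.59 and 0.21 (adjusted p from 2.29e-05 to 8.00e-04). The 7 osteoclast markers tested singly had a median difference of -0.24 with stimulation, with 2 rises, 1 fall and Mmp9 the largest at 5.1. The mean of that list therefore does not stand for most of its markers. B cell (0.02 and -0.06), T and NK cell (-0.08 and 0.02), mast cell (-0.04 and -0.01) and erythroid (0.00 and 0.01) marker means differed by less than 0.1 log2 under either treatment. Of these small differences 4 passed the test: T and NK cell (adjusted p = 2.29e-05) and mast cell markers (0.00264) with stimulation, and B cell (0.00174) and erythroid markers (0.0159) with infection.

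The same limma fit gave these calls, and the median gene lay at -0.01 log2. Against the 5 deep controls alone the count moved to 1933 (839 higher and 1094 lower), of which 940 were among the 1221 and 18 had the opposite sign, so that the balance of rises and falls depended on the controls. The infected libraries were the shallowest, and the labels give the controls no 8 h time point of their own.

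**Figure D2:**
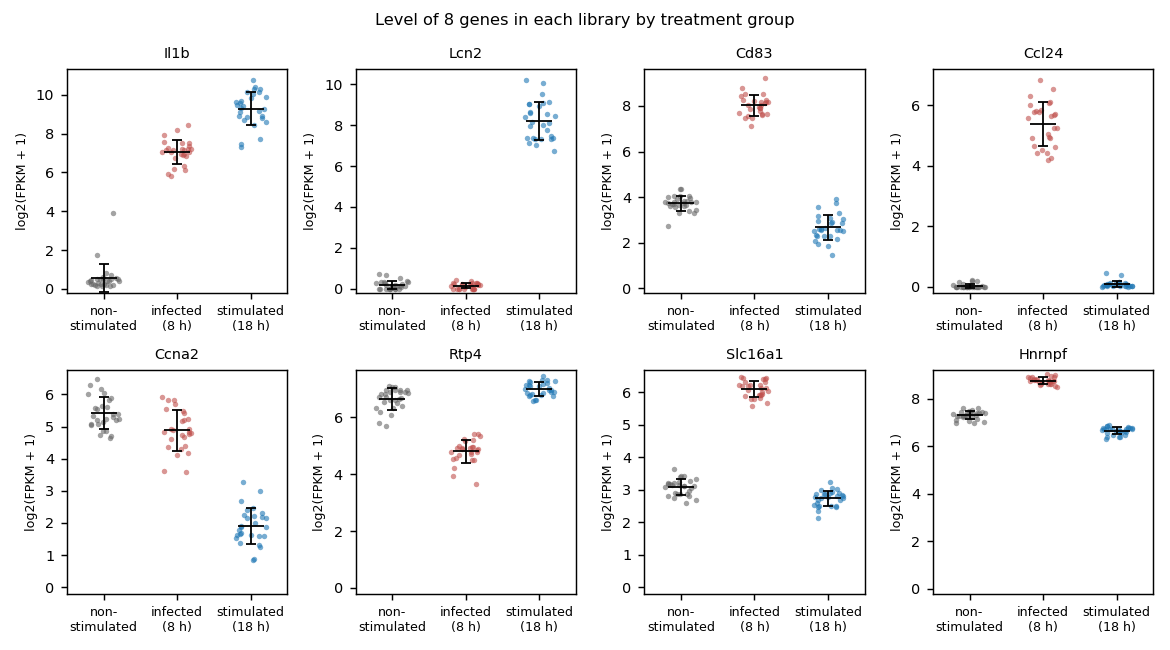
Level of 8 genes, as log2(FPKM + 1), in each library (points) of the non-stimulated, infected and stimulated groups, with the group mean and SD (bar and whisker). Il1b was higher in both treated groups, Cd83 and Ccl24 in the infected group and Lcn2 in the stimulated group, while Ccna2 was lower in the stimulated group.

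The infected and stimulated libraries were also compared directly, a contrast chosen after the duplicate columns were seen, to give the differences that the shared controls cannot test. Lcn2 was lower in the infected libraries (difference -8.07 ± 0.15 log2, SE; adjusted p = 1.52e-63), and Cd83 was higher by 5.36 ± 0.12 (272 ± 94.8 against 5.84 ± 2.89 FPKM). In all, 1579 genes were higher and 799 lower in the infected libraries, or 1255 and 1010 with each library set to the same median and 1154 and 1056 with quantile normalization. The median gene lay at 0.15 log2. Higher in the infected libraries were Ccl24 (5.29 ± 0.11), Adm (4.39 ± 0.12), Phgdh (4.05 ± 0.14), Stmn1 (3.97 ± 0.16) and Hist1h2ao (4.46 ± 0.28), and lower were U90926 (-7.63 ± 0.15), Marco (-7.03 ± 0.17), Ptges (-6.16 ± 0.15), the inducible prostaglandin E synthase, Cfb (-5.70 ± 0.20), complement factor B, Fpr2 (-5.67 ± 0.17), Hp (-5.61 ± 0.17) and Mmp14 (-5.46 ± 0.13). Fth1 was listed at 0 in all 28 stimulated libraries, so that no fold is given for it here either.

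By list, 28 of 30 cell cycle genes were higher and 0 lower with infection than with stimulation (median 2.08, adjusted p = 4.74e-09; adjusted p = 0.805 with an estimated correlation), and so were 14 of 22 cholesterol genes (median 1.24, adjusted p = 3.26e-04; adjusted p = 0.805 with an estimated correlation). Antimicrobial effectors were lower (15 of 25 lower and 1 higher, median -1.68, adjusted p = 6.00e-08, and 0.0486 with an estimated correlation). All 5 neutrophil markers tested, of 16 on the list, were lower too (median -4.92, adjusted p = 8.21e-06, and 0.0207 with an estimated correlation). Of 30 type I interferon-stimulated genes 14 were lower and 0 higher (median -0.87, adjusted p = 7.98e-06; adjusted p = 0.805 with an estimated correlation), led by Mx1 (-2.49 ± 0.19) and Oas2 (-2.42 ± 0.12). The hnRNP list was higher (9 of 35 higher and 2 lower; adjusted p = 0.0154, median 0.66, and 0.33 with quantile normalization; adjusted p = 0.805 with an estimated correlation and 0.094 with quantile normalization). Also lower with infection were the GTPases inducible by interferon gamma (5 of 18 lower and 0 higher; median -0.56, adjusted p = 0.0206; adjusted p = 0.805 with an estimated correlation and 0.0848 with quantile normalization). So were the inflammatory cytokines (6 of 16 lower and 3 higher; median -0.68, adjusted p = 0.0435; adjusted p = 0.805 with an estimated correlation, 0.158 with quantile normalization and 0.0508 with strain as a block). Toll-like receptors and adaptors were lower as a list (4 of 21 lower and 0 higher; median -0.34, adjusted p = 0.0312; adjusted p = 0.805 with an estimated correlation). The same held for inflammasome genes (3 of 19 lower and 1 higher; median -0.32, adjusted p = 0.0276; adjusted p = 0.805 with an estimated correlation). Oxidative phosphorylation genes were higher as a list with 0 of 29 past the size required (adjusted p = 0.0297, median 0.50, and 0.13 with quantile normalization; adjusted p = 0.805 with an estimated correlation and 0.51 with quantile normalization). Genes of the tricarboxylic acid cycle were higher too, 2 of 18 higher and 0 lower (adjusted p = 0.0483, median 0.26, and -0.01 with quantile normalization; adjusted p = 0.805 with an estimated correlation, 0.612 with quantile normalization and 0.0545 with strain as a block). With the 23 other controls in the fit, the cytokine and tricarboxylic acid lists did not pass (adjusted p of 0.0569 and 0.0611). The other 18 lists did not pass in the main fit. The 2 groups differed in duration as well as treatment, and in depth.

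Both responses shared part of their genes. Of all genes tested, 226 rose and 156 fell in both comparisons, where 46.14 and 42.95 would be called in both if the calls were independent, while 17 rose with stimulation and fell with infection and 60 did the reverse. Across genes, which are not independent replicates, the 2 sets of log2 differences had an r of 0.3309. The same 28 controls entered both, and simulated data without any response gave an r of 0.6206 but a covariance of only 0.007642 against 0.2097 in the data. With 14 controls given to each comparison, 229 genes rose and 155 fell in both and r was 0.3491.

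Apobec1, the gene of the editing enzyme that the series is about (mm9 chromosome 6, 122527810 to 122552462), was abundant in every group. It stood at 219 ± 138 FPKM (SD, n = 28) in the non-stimulated, 194 ± 134 (n = 27) in the infected and 156 ± 98.4 (n = 28) in the stimulated libraries. It differed by -0.49 ± 0.25 log2 with stimulation (adjusted p = 0.0637) and -0.27 ± 0.25 with infection (adjusted p = 0.328), neither past the test. With strain as a block, which removes the differences between strains, both passed an adjusted p of 0.05 at -0.49 (adjusted p = 1.57e-06) and -0.30 (adjusted p = 0.00273), below the size required for a call. Among recombinant inbred strains its level ranged from 87.0 FPKM (Axb2) to 493 FPKM (Axb15) without stimulation, and strain accounted for 87.4% of its variation (F = 22, adjusted p = 1.46e-18).

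The partners of APOBEC1 and other editing enzymes were examined as well. Rbm47, an RNA-binding cofactor of APOBEC1, differed by -0.08 ± 0.07 with stimulation (adjusted p = 0.271) and by -0.72 ± 0.07 with infection (adjusted p = 7.88e-17), from 18.5 ± 3.72 to 10.7 ± 1.66 FPKM, below the size required. A1cf, the cofactor first known in the intestine and liver, was not tested, with medians of 0, 0.155 and 0.00413 FPKM in the non-stimulated, infected and stimulated libraries. Apobec3 differed by 0.16 ± 0.14 (adjusted p = 0.287) and 0.83 ± 0.14 (adjusted p = 3.66e-07), and Adar, the adenosine deaminase, by 0.48 ± 0.08 (adjusted p = 4.35e-08) and -0.01 ± 0.08 (adjusted p = 0.93). Of 11 editing enzymes and cofactors tested, Cugbp2 fell with stimulation (-1.06 ± 0.05), while Syncrip (1.05 ± 0.05) and Hnrnpab (1.00 ± 0.05) rose with infection, and the list passed in neither (adjusted p = 0.708 and 0.288). These 3 calls lay near the size required and ended with quantile normalization, at -0.90, 0.98 and 0.90. Against the 5 deep controls Cugbp2 and Syncrip stood at -0.94 and 0.79. Hnrnpab also lost its call with strain as a block and against the 23 other controls (0.95). Of 14 transcripts reported as APOBEC1 targets, 0 passed with stimulation (adjusted p = 0.624) and 1, Dek, with infection (1.00 ± 0.08; 0.89 with quantile normalization and 0.44 against the 5 deep controls, short of the size required, and lost with strain as a block; list adjusted p = 0.685). These are levels of whole genes; editing and splicing themselves were not analysed here. The other genes named in advance were Nos2, the inducible nitric oxide synthase (2.48 ± 0.15 with stimulation, called, and 0.77 ± 0.15 with infection, not called), and Tlr9, the receptor of CpG DNA (-0.46 ± 0.12 and -0.69 ± 0.13, neither called).

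**Figure D3:**
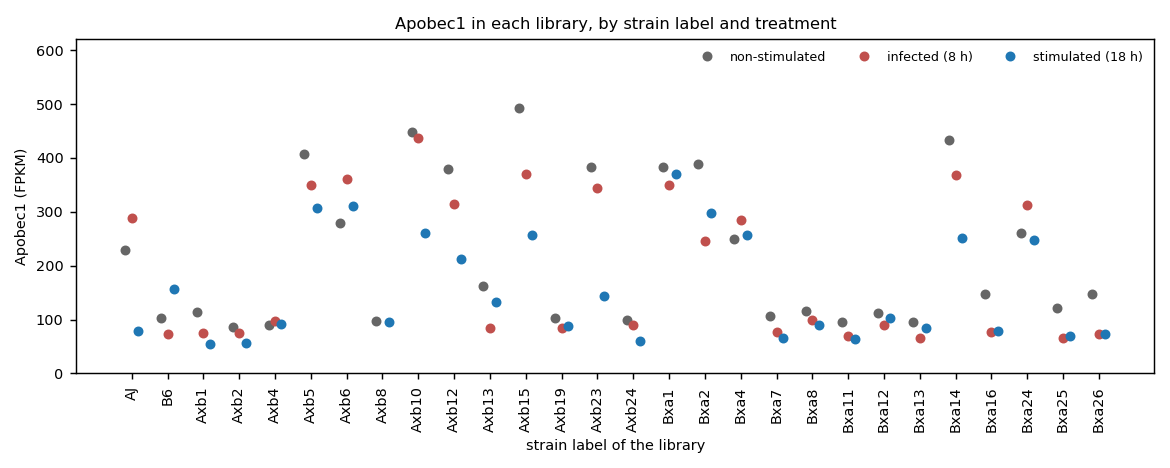
FPKM of Apobec1 in each strain as labelled (horizontal axis), with 1 point per library for the non-stimulated, infected and stimulated treatments. Recombinant inbred strains ranged from 87.0 to 493 FPKM without stimulation, and strain accounted for 87.4% of the variation of the gene.

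The effect of strain was tested over all treatments to find genes whose level follows the genetic background. It passed in 3049 of 11395 genes (26.8%; limma moderated F-test on 27 strain terms). Ifi202b, an interferon-inducible DNA-binding gene, had the largest F of 116.7, and strain accounted for 97.2% of its variation, with 0 to 103 FPKM in the non-stimulated recombinant inbred strains. Other strong examples were Ifi44 (F = 46.6; 1.57 to 234 FPKM), Trim12 (F = 28.5; 0.0696 to 18.2 FPKM) and Uchl1 (F = 26.9; 1.27 to 413 FPKM), a ubiquitin hydrolase best known from neurons. H28 (F = 61.3), AA465934 (F = 58.7), Fggy (F = 39.5), Cd59a (F = 27.1), Bckdhb (F = 26.3), Atp6v0e2 (F = 24.7) and BC022687 (F = 23.9) were the others with the largest F, and Flot2 (F = 50.8), which was at 1.12 FPKM without stimulation in Axb8 against a median of 37.1 FPKM.

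By list, all 18 GTPases inducible by interferon gamma, all 9 MHC class II genes and 27 of 30 type I interferon-stimulated genes had a strain effect. So did 17 of 20 chemokines, 13 of 16 MHC class I genes, 17 of 25 antimicrobial effectors, 18 of 22 cholesterol genes (21 adjusted over the list alone), 23 of 30 cell cycle genes (25 adjusted over the list alone) and 8 of 16 cytokines (10 adjusted over the list alone). The same held for 17 of 25 macrophage identity genes, 10 of 15 LXR targets, 12 of 18 NRF2 targets, 16 of 26 lysosomal and 11 of 18 alternative activation genes. The lowest shares were those of 6 of 28 NF-kB genes (5 adjusted over the list alone), 3 of 19 glycolysis genes, 2 of 35 hnRNPs and other splicing regulators, 0 of 20 SR proteins and 0 of 29 oxidative phosphorylation genes. The other lists with at least 3 tested members lay between 27.8% and 71.4%, and no test compared a list with the 26.8% of all genes. Of 11 editing genes 4 had a strain effect, Apobec1 among them. Without the infected libraries the count of genes was 1219, and without the stimulated libraries 1435. The libraries of a strain may come from 1 animal, which the labels do not say, so that differences between strains and between animals were not separated.

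Strains that were high in interferon-related genes under 1 treatment tended to be high under the others. Over the recombinant inbred strains, the mean of the GTPase list correlated between the non-stimulated and infected libraries (25 strains, Pearson r = 0.75, permutation p = 3.00e-05, adjusted over 12 relations 1.20e-04; Spearman rho = 0.69, p = 2.40e-04). Between the non-stimulated and stimulated libraries it gave r = 0.77 (26 strains, p = 3.00e-05, adjusted 1.20e-04; rho = 0.71, p = 5.00e-05). Without the 2 strains farthest from the median, r was 0.66 and 0.70, and without the 5 strains whose controls were deep 0.78 and 0.74. For type I interferon-stimulated genes r was 0.69 (p = 1.10e-04, adjusted 3.30e-04; rho = 0.68, p = 2.50e-04) and 0.78 (p = 1.00e-05, the smallest possible, adjusted 1.20e-04; rho = 0.71, p = 9.00e-05), or 0.61 and 0.71 without the 2 farthest and 0.70 and 0.78 without the 5. Between the infected and stimulated libraries r was 0.60 for the GTPases (p = 0.00142, adjusted 0.00284; rho = 0.55, p = 0.00526; 0.56 without the 2 farthest) and 0.62 for the interferon-stimulated genes (p = 0.00102, adjusted 0.00245; rho = 0.61, p = 0.0015; 0.69 without the 2 farthest). For inflammatory cytokines r with the non-stimulated level was 0.37 (p = 0.0699, adjusted 0.105; rho = 0.25, p = 0.22) and 0.28 (p = 0.157, adjusted 0.188; rho = 0.14, p = 0.492). It was 0.72 and 0.65 without the 5 strains whose controls were deep (adjusted p = 9.36e-04 and 0.00348). Their r between infected and stimulated libraries was 0.41 (p = 0.0408, adjusted 0.07; rho = 0.31, p = 0.133). For SR proteins r was 0.30, 0.15 and 0.17 over the 3 pairs of treatments (p = 0.14, 0.459 and 0.429, adjusted 0.187, 0.459 and 0.459; rho 0.27, 0.14 and 0.12).

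Treatment accounted for a median of 52.0% of the variation of a gene (SE 3.3), strain for 19.4% (SE 1.0) and the residual for 25% (SE 2.6), with treatment above 50% in 5996 genes and strain in 637. Il1b was mostly a matter of treatment (96.3%). Without a filter on low values the medians were 27.6%, 27.5% and 39.8%. The 27 strain terms take up part of the variation even where strain has no effect, and this part was not subtracted. The strain shares therefore overstate the part that strain itself explains.

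The 2 parents, AJ and B6, were compared to see which strain differences of the panel separate its founders. As labelled, 0 genes were called by limma between B6 and AJ (907 at an unadjusted p under 0.05). Without the stimulated libraries 188 genes were called, 132 higher and 56 lower in B6. Hk3, a hexokinase of myeloid cells, was higher in B6 by 3.94 log2 (SE 0.21, adjusted p = 1.99e-14), at 81.3 and 53.1 FPKM in the non-stimulated and infected libraries of B6 against 3.59 and 3.13 FPKM in those of AJ. Glo1, glyoxalase 1, was lower in B6 (difference -1.88, SE 0.24, adjusted p = 4.31e-06), and so was Apobec1 (-1.56, SE 0.27, adjusted p = 4.53e-04). In the stimulated library labelled AJ, however, Hk3 stood at 109 FPKM and in that labelled B6 at 20.1 FPKM, the reverse of the other treatments.

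The other genes higher in B6 without the stimulated libraries were the complement genes C1qb (5.25), C1qa (4.04) and C1qc (3.38), Ly6a (3.34), Ifi205 (3.31), Trim12 (3.13) and AF251705 (3.07). The other genes lower in B6 were Atp6v0e2 (-4.43), Rpl38 (-3.26), Ass1 (-2.41), BC022687 (-2.14), Ugt1a6b (-2.10), Ifi202b (-1.91) and Ada (-1.83). Among genes polymorphic between the parents, Gbp1 (-1.73, adjusted p = 0.0498) and Wdfy1 (-1.13, adjusted p = 0.00178) were called, and Entpd4 (0.95, adjusted p = 0.0072), Nnt (-0.27, adjusted p = 0.671) and Apobec3 (1.05, adjusted p = 0.151) were not. Of the 188 genes, 177 had the opposite direction in the pair of stimulated libraries labelled AJ and B6, 90 of them by at least 1 log2. Each parent had 1 library per treatment, so the spread came from all strains. The non-stimulated AJ library had the lowest FPKM sum of all libraries (367243.7), 15 abundant genes listed at 0 and no depth estimate. The parental calls rest in part on it. Rpl38 stood at 283 and 1443.1 FPKM in the non-stimulated and infected AJ libraries. Its means in the AxB and BxA strains were 93.3 and 104 FPKM without stimulation and 106 and 92.1 FPKM with infection.

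**Figure D4:**
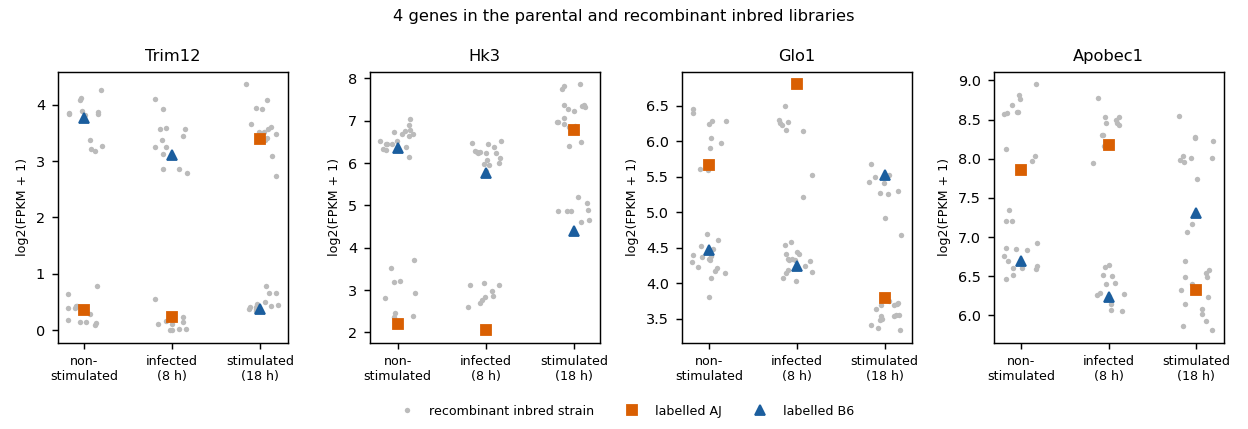
Level of Trim12, Hk3, Glo1 and Apobec1, as log2(FPKM + 1), in the recombinant inbred strains (grey points) and in the libraries labelled AJ (orange squares) and B6 (blue triangles) under each treatment. In the stimulated group the libraries labelled AJ and B6 lay on the opposite sides to those of the other treatments.

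The 2 directions of the cross were compared over the 26 recombinant inbred strains, where a gene was called on its adjusted p alone, whatever the size of the difference. The predicted gene 1810022K09Rik was lower in BxA than in AxB strains (difference -0.37 log2, SE 0.06, adjusted p = 0.0232), the only gene of 11395 called, with 501 at an unadjusted p under 0.05. It was not called with each library set to the same median or without the library titled Bxa26 that carries the strain tag Bxa25. Its means in AxB and BxA strains were 15.9 and 7.61 FPKM with stimulation, 20.8 and 20.2 without it and 25.9 and 23.8 with infection. The difference thus lay mainly in the stimulated libraries. The genes next in order were Gm11836 (-0.37) and Gm11189 (0.37), both with an adjusted p of 0.248. By treatment, limma called 0 genes in the non-stimulated libraries (92 at an unadjusted p under 0.05), 0 in the infected (220) and 2179 in the stimulated (1526 higher and 653 lower in BxA). The median absolute difference of those 2179 genes was 0.2 log2 and only 22 differed by at least 1, so that their number does not compare with the calls between treatments or parents. Of the 2179, 14 and 29 had the same sign at an unadjusted p under 0.05 in the non-stimulated and infected libraries.

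The response itself differed between the crosses at 15 genes for stimulation and 0 for infection (95 at an unadjusted p under 0.05, limma). Of the 15, called on adjusted p alone as well, 9 differed by at least 1 log2. The 15 became 8 without a filter, 5 with a minimum of 5 FPKM, 9 with median scaling and 29 with quantile normalization. Il6, a fever-inducing cytokine, responded less in BxA strains (difference -1.28 log2, SE 0.24, adjusted p = 0.02), at 5.94 ± 3.49 FPKM (SD, n = 13) with stimulation against 16.2 ± 7.2 in AxB strains (n = 13). With stimulation the ribosomal protein genes Rpl39 and Rpl38 and the cytochrome oxidase gene Cox8a fell in both crosses, and fell further in BxA strains. Their differences were -1.75 (SE 0.25, adjusted p = 0.00124), -1.22 and -1.14 (adjusted p = 0.0242). The mean of Rpl39 went from 127 to 66.3 FPKM in AxB and from 149 to 22.4 FPKM in BxA strains. In the stimulated library of the AxB strain Axb24, Rpl39 stood at 19.7 and Cox8a at 38.9 FPKM, below the BxA means of 22.4 and 42.9 FPKM. Across genes, the difference between the crosses in the stimulated libraries also rose with transcript length (rho = 0.31). A further fall in BxA strains was therefore not separated from a difference between libraries. Rn18s, the ribosomal RNA, was also called, but it was listed at 0 in every AxB stimulated library and at 7143.9 to 9902.6 FPKM in 8 BxA libraries. Its fitted difference of 8.51 log2 (SE 1.79) is therefore not read as a fold, although the gene is counted among the 15 and among the 9. Of the 15 genes, 14 were also called between the crosses in the stimulated libraries alone.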

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

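The tests of explanations in this part were chosen only after the results they address had been seen, while the comparison of cross by treatment had been fixed in advance.

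The stimulated libraries labelled AJ and B6 differed from each other in the opposite direction to the other parental libraries, at 177 of 188 genes. A true reversal under stimulation is argued against, because over the recombinant inbred strains the stimulated level of these genes followed their level under the other treatments (median r = 0.85). Libraries of some other strain in place of both are argued against as well: over 500 genes chosen without the stimulated libraries, the library labelled AJ correlated at 0.75 with the other B6 libraries and at -0.35 with its own, and the library labelled B6 at 0.686 with the AJ libraries and at -0.584 with its own. An exchange of these 2 labels is a candidate explanation, since each of the 2 correlated best with the other libraries of its partner's label (0.75 and 0.686), which could have come out otherwise. The 6 parental libraries make only 10 splits, too few for a share under 0.05, with a real value of 0 and 208 as the highest of the others, given by the split that exchanges the stimulated pair.

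The response to stimulation differed between the BxA and AxB strains at 15 genes, a difference between groups found by the interaction test, and 2179 genes differed between them in the stimulated libraries alone, both on adjusted p without a minimum size. Chance is unlikely for both in the main setting, since 1 of 100 splits of the strains, the real one, gave as many (highest other 4 and 9). The splits were not repeated under the alternatives, which moved the count of 15 genes. Library or sequencing batches that followed the cross are a candidate explanation, as the difference rose with transcript length across genes (rho = 0.31) and ribosomal RNA (Rn18s) was listed at 0 in every AxB library and above 0 in 8 BxA libraries. A difference already present without stimulation cannot be told apart from none, since the median non-stimulated difference of the 2179 genes was 0.03 (SD 0.09 over regroupings) against 0.2 with stimulation. A difference between the crosses in the response cannot be told apart from such batches either. The Axb24 library scored 0.63 on the BxA side and its Rpl39 was 19.7 FPKM (44.7 to 105 in the other AxB libraries). Its Il6, however, was 23.7 FPKM, above every BxA library (at most 16.0). Both parents, with 1 library each, lay on the AxB side (AJ -1.26 and B6 -1.55) and not between the crosses. A place between them had been the prediction for such a response, written after the results were seen. The design does not fix where the parents should lie, so their place decides nothing.

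Ddx3y, a Y-linked gene below the filter of every comparison, had a median of 0.112 FPKM in the infected libraries, although the mice were female. There 27 of 27 libraries were above 0. The control median was 0, with 11 of 28 controls above 0 (at most 0.0231 FPKM). In the stimulated libraries 19 of 28 were above 0 (at most 0.00842 FPKM). Infection switching on Y-linked genes of these macrophages is argued against, since Xist, which marks cells with 2 X chromosomes, had a median of 18.6 FPKM in the infected libraries and at least 10.5 in all but that of Axb5, where at 0.0166 FPKM of Xist and 0.0648 of Ddx3y it cannot be told apart from another source. RNA of cells of another individual is a candidate explanation, as the summed level of 4 Y-linked genes correlated with the mean of 15 fibroblast markers over the infected libraries (r = 0.81, permutation p = 4.00e-05; rho = 0.60, p = 9.60e-04), and at 0.55 (p = 0.00445) without Bxa2 and Bxa11, the 2 farthest. Induction of the fibroblast genes by infection cannot be told apart from such cells, as Col1a1 (median 0.488 FPKM), Col1a2 (0.773), Mmp2 (2.72) and Fbln1 (1.99) were all low. Cells in which a parasite was grown are a source that the labels do not describe and that was not tested.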

How the results depend on the processing

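Among the main results, a count was labelled the same if it lay within a set factor of the main count, whatever its balance of rises and falls. A variance share was labelled the same within its standard error. A correlation or the Apobec1 level was labelled the same if it kept its direction and side of the threshold. Under alternatives fixed in advance, 98 values were the same, 22 moved and 2 became stronger. Under those chosen after seeing the data (the control sets, missing values and left-out libraries), 48 were the same, 11 moved and 4 became stronger. For named genes and lists the alternatives fixed in advance gave 2750 values with the same call, 63 stronger and 51 weaker, and the added ones 3010, 52 and 57, with 2 reversed. Where no cause is given, the cause was not tested. The depth limits what infected libraries can show at low levels, and stimulation, depth and control set overlap.

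Without a minimum difference, 9073, 8455 and 9325 genes passed for stimulated, infected and infected against stimulated, as more genes can pass. Other alternatives gave 1426 to 2256, 982 to 1690 and 1960 to 3074, except that with the 5 deep controls alone 1933 passed for infected, and Cox4i1 and Abca1 reversed to 0.31 and -0.07. With strain as a block Apobec1 passed at -0.49 and -0.30 (and at -0.40 and -0.21 with the 23 other controls and the block; other settings gave -0.51 to -0.16 and -0.35 to -0.27), which the block explains by construction, since it removes the strain differences. The block let 2 more list tests against the controls pass (25 against 23), ended the call of Dek and Hnrnpab in the infected libraries and gave that of Txnrd1 between infected and stimulated libraries. Between infected and stimulated libraries it ended the call of the cytokine list (adjusted p from 0.0435 to 0.0508) and of the tricarboxylic acid cycle list (0.0483 to 0.0545), and it changed no other call of a named gene or list. Of the 60 list tests against the controls 23 were called, 7 with an estimated correlation and 45 with fry, which tests another question.

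Between B6 and AJ, 188 genes passed without the stimulated libraries, 264 without the 2 stimulated parental libraries, 3 without a filter, 0 without the infected libraries and 1 without the non-stimulated libraries or in the fit of the 4 non-stimulated and infected parental libraries alone. The strain effect gave 1219 without the infected, 1435 without the stimulated and 2453 without the non-stimulated libraries, where fewer libraries were tested, and 2132 to 3800 otherwise. Between the crosses, the count of 1 became 2 without a filter, with zeros missing or without the infected libraries of Bxa2 and Bxa11, 0 with median scaling or without the stimulated library of Bxa26, 3 with the deep controls as a level of their own, 6 without them, 0 in the non-stimulated or infected libraries alone, and 2179 in the stimulated alone (2057 with median scaling and 2075 with quantile normalization). The 15 genes of cross by treatment became 8 without a filter, 5 with a minimum of 5 FPKM, 9 with median scaling and 29 with quantile normalization. Without a filter the shares of treatment, strain and residual were 27.6%, 27.5% and 39.8% and with a minimum of 5 FPKM the strain share was 18.2%. Without the 5 strains with deep controls, the cytokine list correlated at 0.72 and 0.65 with the non-stimulated level. The library identity check gave 76 or 77 of 83. The comparison of IFN/TNF with CpG and its alternatives could not be run, nor could a parental fit with 4 treatments.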

Other observations

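The tests of neighbouring genes, of Apobec1 and of other splits were chosen only after the results had been seen.

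Genes with a strong strain effect that lie near each other varied together over the recombinant inbred strains. Among the 500 genes with the largest strain effect, the median absolute correlation was 0.52 for pairs 1 to 5 Mb apart (permutation p = 9.99e-04, the smallest possible with 1000, and highest permuted median 0.19). It was 0.76 under 1 Mb, 0.38 at 5 to 20 Mb and 0.16 on different chromosomes, for which no p is given. This is consistent with parental segments that neighbouring genes share. Apobec1 behaved alike: its level had a median absolute correlation of 0.63 with 9 strain-effect genes 1 to 20 Mb away against 0.18 with 472 genes on other chromosomes (p = 1.00e-04, the smallest possible with 10000 random sets). The genes most correlated with it, Eno2 (0.87), C530028O21Rik (0.87) and BC064078 (0.80), lie on chromosome 6 too, as do 6 of the 12 most correlated. The others are on the X chromosome (Mid1, -0.76, the fourth, and G530011O06Rik, -0.67, both listed at the same span) and on chromosomes 1 and 5, so that neighbourhood does not account for all of them. Some of the 12 share a locus or lie close together, as Gbp10 and Gbp4 do on chromosome 5. The 12 are therefore not separate loci. A parental segment around Apobec1 may carry its strain difference, as a hypothesis.

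The genes in this paragraph were chosen after their values were seen, and no test was made of them as a group. In the stimulated libraries Cxcl9 had a median of 0.0729 FPKM against 0.0902 FPKM in the controls, Ido1 0.0531 against 0, and Ciita, the master regulator of MHC class II, 0.999 against 0.157. The medians of 3 cytokines were 7.67 FPKM for Il6, 2.61 FPKM for Il12b and 79.9 FPKM for Tnf against 0, 0 and 8.81 FPKM.

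Xist stood at 17.7 FPKM in the non-stimulated library of Axb5 and at 0.0166 and 0.0822 FPKM in its infected and stimulated libraries, where the other infected and stimulated libraries held at least 10.5 and 49.4 FPKM. The IFN/TNF library titled Bxa26 correlated at 0.665 with the other Bxa26 libraries and at most at 0.317 with another strain. The stimulated library of Axb19 correlated at 0.496 with its own strain and at 0.598 with the libraries labelled B6. In 100 random pairs of recombinant inbred strains, a fit without the stimulated libraries called a median of 112 genes (30 to 692), and 12 pairs had as many as the 188 of the parents.

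Other splits of the same libraries bear on the counts of calls. Chance is unlikely for the stimulated libraries, where 1 of 100 splits, the real one, gave as many as 1739 (highest other 17). The same holds for the infected libraries (1 of 100 for 1221, highest other 24). With labels swapped within strains, which keeps the pairs, the highest others were 381 and 337 (1 of 100 each). Chance is unlikely too for infected against stimulated (1 of 100 for 2378, highest other 143) and the strain effect (1 of 100 for 3049, highest other 2). The smallest share that 100 splits can give is 1 of 100. For BxA against AxB 2 of 100 splits, the real one included, gave the real value of 1 gene, the highest of the others being 1 as well. For the response to infection by cross the real value was 0, which all 100 of 100 splits reach whatever the data, so that the splits say nothing about it and chance is not excluded (highest other 1).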
